A study of Mus musculus with 3 samples.

How the data were processed

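RNA was measured in 3 libraries from mouse primary pre-osteoclasts, the mononuclear precursors that express tartrate-resistant acid phosphatase and later fuse into bone-resorbing osteoclasts. Per the labels' protocols, cells carrying a control or an Ift88 short hairpin RNA (shRNA) were cultured with MCSF and RANKL for 2 days. Dishes in the sheared groups then received orbital shear stress, fluid flow produced by swirling the dish, for 24 hours before RNA was extracted with TRIzol. Libraries were made with the Illumina TruSeq mRNA kit, which selects polyadenylated RNA, per the labels' protocols. The 3 groups were static cells with control shRNA, sheared cells with control shRNA and sheared cells with Ift88 shRNA, with 1 library in each. Static cells with Ift88 shRNA were not analysed here, so an effect of the knockdown that is independent of shear and an effect that depends on shear cannot be separated.

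The values are FPKM, fragments per kilobase of transcript, scaled to the mapped fragments of the library, as deposited by the authors in 1 table of 24067 genes. The submitters' processing notes name bcl2fastq 1.8.4, Trimmomatic 0.32, TopHat2 2.0.13 and Cufflinks 2.2.1, with the mouse build mm10. The settings of these tools and the treatment of strand are not given in the sources used here. Each gene carries an NCBI gene ID, a symbol and RefSeq transcripts in the deposited table. Of the gene IDs, 23987 matched the RefSeq gene table of the same build (GRCm38), which gave the coordinates. For 131 genes without a symbol, the gene ID was kept, and 8 of these passed the expression filter. FPKM is a share of each library, so a difference in a few abundant genes moves all others, and for a gene shorter than a fragment a few fragments give a large FPKM. Cufflinks divides fragments between near-identical gene copies by estimation, so genes with such copies are reported as uncertain.

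Sequencing depth was estimated from the spacing of low FPKM values among genes with 1 transcript of at least 1000 bases, where 1 fragment adds a fixed step that depends on length. This gave 35097105 fragments for the static library, 35319216 for the sheared control library and 35149400 for the sheared Ift88 shRNA library. Of the low values, up to 10 fragments, 64.4%, 63.5% and 63.5% were whole numbers of fragments within 0.1, so the fragment numbers are estimates and no count model was applied. Estimated fragments were computed for genes whose shortest transcript exceeded 500 bases. Ratios of FPKM are given with 95% Clopper-Pearson intervals from these estimates. The intervals cover counting error only, not the variation between cultures or between library preparations.

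Ratios were computed as log2 of (FPKM + 1) in one library over (FPKM + 1) in another, a scale that understates the differences of low genes. Genes with a mean FPKM of at least 1 over the 3 libraries were kept, which left 10358 genes. A gene was counted when it differed by at least 2-fold on this scale. No p-value was computed, because each group had 1 library and genes are not replicates of a condition. Every difference therefore has no replicate check and describes these libraries. Folds given beside genes are ratios of FPKM without the added 1.

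The gene lists were fixed before the data were examined. The 31 lists covered osteoclast differentiation and resorption, negative regulators of osteoclast formation, monocyte and macrophage markers, dendritic cell and antigen presentation, intraflagellar transport and cilium, the Hedgehog pathway, mechanosensitive channels and receptors, YAP and TAZ targets, immediate early genes and osteoclast-derived coupling factors. They also covered the Wnt pathway, the BMP and TGF-beta pathway, inflammatory cytokines and chemokines, interferon-stimulated genes, cell cycle, cell fusion and adhesion, extracellular matrix and proteases, hypoxia and glycolysis, NRF2 targets, unfolded protein and integrated stress response, cholesterol synthesis and lipid handling, and p53 targets. The remaining lists were actin cytoskeleton, oxidative phosphorylation, cytosolic ribosomal proteins, osteoblast and stromal markers, neutrophil markers, lymphoid markers, erythroid with mast cell and megakaryocyte markers, endothelial markers and housekeeping controls. Of 855 listed symbols, 6 had no match in the table. Each list's median log2 ratio was placed among the medians of 10000 random lists of the same size, matched in 20 bins of mean expression. A list is said to stand apart when its percentile was below 2.5 or above 97.5. Some lists share members, so lists standing apart are not all separate results. Random lists treat genes as independent, whereas genes of a pathway vary together between any pair of cultures, so a percentile is a description of these libraries. For 3 lists (lymphoid, endothelial, and erythroid with mast cell and megakaryocyte) fewer than 3 members passed the filter, and 28 lists were placed.

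The genes named were Ift88, up to 12 genes with the highest and 12 with the lowest ratio of at least 2-fold in each main comparison (leaving out small RNA genes and provisional symbols), the 4 members of each list with the largest absolute ratio, and genes that differed by at least 2-fold in opposite directions in both comparisons. Members of cell type lists were also allowed. A few genes that the rule would name are not reported here. Genes outside this rule are marked in the text as chosen after their values were seen, except copies or overlapping genes given beside an uncertain value. The comparison of the sheared control library with the static library and that of the sheared Ift88 shRNA library with the sheared control library share a library with opposite sign. The correlation, covariance and shares of reversed genes were therefore set beside 100 simulated sets of 3 unchanged libraries. Their noise was normal on the log2 scale, with an SD taken from the middle of the observed ratios at like mean expression. It therefore includes any widespread difference between these libraries. The alternatives tried were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, equal library totals, and median-of-ratios scaling. Added after the data were seen were leaving out small RNA genes, a 1.5-fold limit, and ratios centred in 10 by 10 bins of transcript length and GC content (99.1% of the kept genes had a length).

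The steps were tested on simulated data for 10130 genes. For the comparison of sheared with static cells, 90 of 100 genes changed 3-fold and 94 of 100 changed 4-fold were recovered. For the comparison of Ift88 with control shRNA, 93 and 98 of 100 were recovered. None of the 9930 unchanged genes was called in either comparison. Of 200 unchanged lists of 25 genes, 10 stood apart in the simulated shear comparison and 8 in the simulated knockdown comparison. The real shear ratios spread more widely than counting error alone (robust SD 0.109 against 0.0536 over the genes with estimated fragments). The simulations therefore do not give the rate of false calls in the real libraries, and they leave out short RNA genes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.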

Results

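Gene expression was profiled by mRNA sequencing in primary mouse pre-osteoclasts to ask how these cells respond to orbital shear stress and what part Ift88 has in that response. Ift88 encodes a component of the intraflagellar transport machinery that builds and maintains the primary cilium. The 3 groups were static cells with control shRNA, sheared cells with control shRNA, and sheared cells with Ift88 shRNA, each represented by 1 library. Estimated depth was close to equal, at 35097105, 35319216 and 35149400 fragments, and 10354, 10304 and 10358 genes reached an FPKM of 1. With 1 library per group, no p-value is given, no difference has a replicate check, and the intervals in brackets are 95% counting intervals from estimated fragments.

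Ift88 (gene ID 21821, chromosome 14, 57424064 to 57517936 in GRCm38) was measured at 2.98 FPKM in the static control library, 2.71 in the sheared control library and 1.197 in the sheared Ift88 shRNA library. The level with Ift88 shRNA was 0.442 times that of the sheared control (0.354 to 0.549), in the direction the label gives. The sheared control library stood at 0.908 times the static library, with an interval of 0.768 to 1.07 that includes no difference. These values rest on an estimated 302, 277 and 122 fragments.

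The shear comparison set sheared against static cells, both with control shRNA. Ctsk, Acp5, Mmp9 and Slc9b2, members of the osteoclast list, were lower in the sheared library. Ctsk, the main collagen-degrading protease of osteoclasts (chromosome 3, 95499210 to 95509387), was at 29.4 FPKM in static and 12.6 in sheared cells, a ratio of 0.428 (0.388 to 0.472). Acp5, which encodes tartrate-resistant acid phosphatase, was at 97.7 FPKM in the static and 52.9 in the sheared library, a ratio of 0.542 (0.514 to 0.571). The matrix protease Mmp9 was at 70.3 and 39.3 FPKM, a ratio of 0.559 (0.538 to 0.580). Slc9b2, a sodium/proton antiporter associated with osteoclast differentiation, was at 1.75 and 0.550 FPKM.

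Of the 27 measured members of the osteoclast list, 21 were lower and 6 higher in sheared cells, with a median log2 ratio of -0.080 (percentile 0.05 among random lists). With a mean FPKM of at least 5 the median was -0.042 (percentile 1.69). The difference was concentrated in a few genes, with 4 of 27 members at least 1.5-fold lower. The transcription factor genes Nfatc1 (16.2 and 15.3 FPKM) and Mitf (16.6 and 15.7), which direct osteoclast differentiation, and the proton pump subunit gene Tcirg1 (406 and 395) had nearly equal levels. Itgb3, a subunit of the vitronectin receptor, was higher in sheared cells, at 7.08 against 5.36 FPKM. Nfatc1, Mitf and Tcirg1 lie outside the rule for named genes and were chosen after their values were seen. The fusion and adhesion list, which shares Dcstamp and Itgb3 with the osteoclast list, was lower too (15 of 22 members, median -0.061, percentile 0.35). Its member Dcstamp, needed for precursor fusion, was at 5.21 FPKM in static and 3.67 in sheared cells. The extracellular matrix and protease list was lower in 18 of 25 members (median -0.14, below every random list); it shares Ctsk and Mmp9 with the osteoclast list and Col1a1, Col1a2 and Sparc with the stromal list.

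Markers of other cell types were lower in the same library. Neutrophil markers were lower in all 5 measured members, with a median of -0.89, below every random list. The size of that median depended on the members kept, at -0.51 with a mean FPKM of at least 5 and -0.15 without the filter, both below every random list. S100a9, an abundant calcium-binding protein of neutrophils, was at 22.3 FPKM in static and 6.66 in sheared cells, a ratio of 0.298 (0.228 to 0.386), and the granule gene Ngp was at 4.36 and 1.01. Csf3r (15.6 and 14.4 FPKM) and Mmp8 (9.09 and 8.22) differed little. The stromal list was lower in 6 of 7 members (median -0.24, percentile 0.08), with Col1a1 at 2.80 and 1.76 FPKM. That stromal result was lost without the expression filter, where the median was -0.022 (percentile 9.83). Monocyte and macrophage markers were lower in 12 of 16 members (median -0.10, below every random list), among them the complement gene C1qb at 38.5 and 30.04 FPKM. The dendritic cell and antigen presentation list was lower in 8 of 10 members (median -0.15, percentile 0.02), with the MHC class II gene H2-Aa at 13.6 and 10.54 FPKM; without the filter its percentile was 10.9. Too few members passed the filter to place the other cell type lists. Their measured members were Cd4 (15.2 FPKM in static and 12.3 in sheared cells), Pf4 (307 and 309), Kdr (5.63 and 4.83) and Vwf (22.8 and 21.8).

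Interferon-stimulated genes, the antiviral program downstream of type I interferon, were lower in sheared cells in 31 of 32 members. Their median log2 ratio was -0.24, below every random list. The GTPase gene Mx1 was at 4.94 FPKM in static and 2.70 in sheared cells, a ratio of 0.547 (0.464 to 0.641). Ifit2 was at 8.71 and 5.35 FPKM, Ifit3 at 16.0 and 10.7, and Rsad2, which encodes viperin, at 17.7 and 12.3. Inflammatory cytokine and chemokine genes were lower in 14 of 17 members (median -0.089, percentile 0.41). In that list the neutrophil-attracting chemokine Cxcl2 was at 2.53 FPKM in static and 1.13 in sheared cells, and the chemokine Ccl6 at 124 and 96.8.

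Several biosynthetic and proliferative groups were higher in sheared cells. The cholesterol and lipid list was higher in 21 of 30 members (median 0.12, above every random list). Fdft1, which encodes squalene synthase, was at 8.31 FPKM in static and 11.4 in sheared cells, and Mvd, an enzyme of the mevalonate pathway, at 20.5 and 25.7. In the same list Abca1, which exports cholesterol, was lower, at 14.5 and 10.51 FPKM. Cell cycle genes were higher in 25 of 34 members (median 0.093, above every random list), with the mitotic cyclin Ccnb2 at 10.1 and 14.2 FPKM and the ubiquitin-conjugating enzyme gene Ube2c at 16.9 and 22.4. The unfolded protein and integrated stress response list was higher in 19 of 26 members (median 0.10, percentile 99.98). Its leading members were Phgdh and Psat1, enzymes of serine synthesis (3.999 and 5.71 FPKM; 7.97 and 9.93), the mitochondrial folate enzyme gene Mthfd2 (11.6 and 14.7) and the amino acid transporter gene Slc7a5 (3.36 and 4.79).

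NRF2 targets, which encode antioxidant enzymes, were higher in 20 of 26 members (median 0.070, percentile 98.6), with Nqo1 at 2.85 FPKM in static and 4.28 in sheared cells. With a mean FPKM of at least 5 that percentile was 97.2, inside the range of random lists. Ribosomal protein genes were higher in 31 of 32 members (median 0.094, percentile 99.4), with Rpl19 at 952 and 1092 FPKM. After centring in bins of transcript length and GC content the ribosomal median was 0.035 (percentile 85.7), no longer apart. Across genes, the shear ratio had a Spearman correlation of -0.28 with transcript length and 0.34 with GC content.

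The other 14 lists that could be placed lay within the range of random lists in the shear comparison. Of these, hypoxia and glycolysis stood apart on the higher side in 4 of 8 alternatives, immediate early genes on the lower side in 2 of 8 and coupling factors on the lower side in 1 of 8. Cilium genes were split evenly, with 18 of 35 members higher (median 0.0011), as were mechanosensitive channels and receptors, with 7 of 14 higher (median 0.0090). Panx1, a channel that releases ATP, was at 16.1 FPKM in static and 19.2 in sheared cells, and the integrin gene Itgav at 10.3 and 8.37. YAP and TAZ targets had a median of -0.050, immediate early genes -0.045 and osteoclast-derived coupling factors -0.045. Medians were -0.012 for the Hedgehog pathway, -0.059 for the Wnt pathway, -0.040 for the BMP and TGF-beta pathway and -0.0057 for negative regulators of osteoclast formation. They were 0.042 for hypoxia and glycolysis, -0.034 for p53 targets, -0.010 for actin cytoskeleton, 0.056 for oxidative phosphorylation and 0.0018 for housekeeping controls.

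Among single genes, 12 were at least 2-fold higher and 17 at least 2-fold lower in sheared than in static cells, of 10358 genes. Of these, 8 in each direction were small RNA genes, leaving 4 higher and 9 lower. The metallothionein gene Mt3 was at 5.63 FPKM in static and 1.99 in sheared cells (ratio 0.354, 0.216 to 0.573). Chil3, a chitinase-like protein of myeloid cells, was at 4.32 and 1.46 FPKM. Pet117, which encodes a mitochondrial assembly factor, was at 0.418 and 2.97 FPKM, but it overlaps Csrp2bp (14.4 and 14.2 FPKM) and its value is uncertain. The pair Eif3j1 (18.8 and 8.26 FPKM) and Eif3j2 (2.28 and 11.1), near-identical copies of a translation initiation factor subunit gene, went in opposite directions while their sum was 21.1 and 19.3, so each value is uncertain. H2-Q6 (0.0406 and 1.86 FPKM), a class I histocompatibility gene, and the pseudogene Apoo-ps (1.11 and 4.25) are uncertain for the same reason.

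The shear differences were small against the whole distribution, with 95.8% of genes within 1.2-fold. Of the 28 lists placed, 14 stood apart, 9 lower and 5 higher, where 1.4 would by chance if genes were independent, and 10 of them did so under every alternative. The robust SD of the log2 ratio across genes was 0.111, and counting error alone would give 0.0536 over the genes with estimated fragments. That spread includes differences between single cultures as well as any effect of shear.

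**Figure D1:**
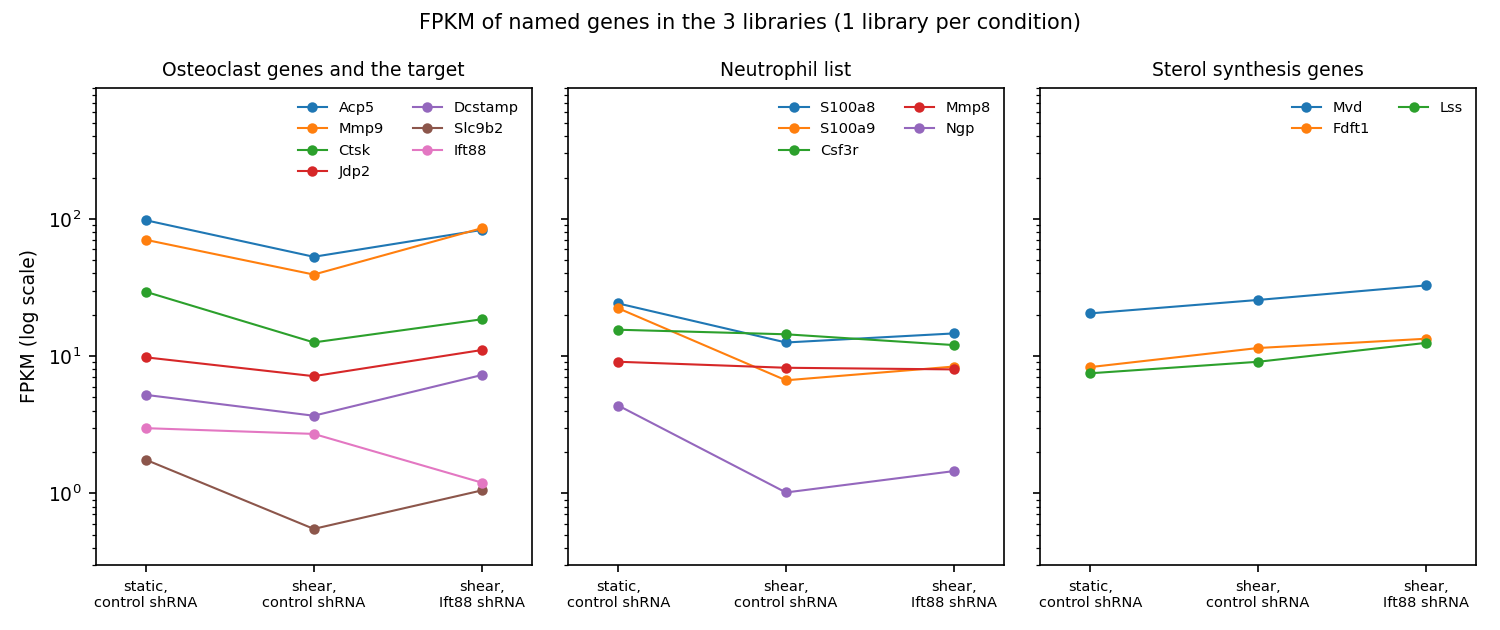
FPKM of osteoclast genes with Ift88, neutrophil list genes and sterol synthesis genes, in separate panels (vertical axis, logarithmic), in the static control shRNA, sheared control shRNA and sheared Ift88 shRNA libraries, with 1 point per library and lines joining the values of a gene. Acp5, for example, was at 97.7, 52.9 and 83.0 FPKM, and S100a9 at 22.3, 6.66 and 8.38.

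The knockdown comparison set sheared cells with Ift88 shRNA against sheared cells with control shRNA. Several osteoclast genes were higher in the Ift88 shRNA library. Mmp9 was at 85.5 FPKM against 39.3 in the sheared control, a ratio of 2.18 (2.10 to 2.26). Dcstamp was at 7.27 against 3.67 FPKM, a ratio of 1.98 (1.62 to 2.42). Acp5 was at 83.0 against 52.9 FPKM (ratio 1.57, 1.49 to 1.66), Ctsk at 18.5 against 12.6 (ratio 1.47, 1.33 to 1.64), and Jdp2, a transcription factor gene of osteoclast differentiation, at 11.1 against 7.14 (ratio 1.55, 1.350 to 1.78).

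The osteoclast list was higher in 19 of 27 members with Ift88 shRNA (median 0.070, percentile 99.8). An exception was Snx10, a sorting nexin gene needed for resorption, at 21.8 FPKM against 32.0; it lies outside the rule for named genes and was chosen after its values were seen. The fusion and adhesion list, which shares Dcstamp and Itgb3 with the osteoclast list, was higher in 14 of 22 members (median 0.082, percentile 99.96). Its member Itgav was at 11.5 against 8.37 FPKM. Extracellular matrix and protease genes were higher in 17 of 25 (median 0.24, above every random list; 0.061 without the filter, percentile 99.6), including the protease inhibitor Timp1 at 7.07 against 4.74 FPKM, while the matricellular gene Thbs1 was lower, at 6.68 against 9.72.

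Stromal markers moved with these lists. They were higher with Ift88 shRNA in 6 of 7 members (median 0.27, percentile 99.96), with Sparc at 2.67 against 1.797 FPKM and Col1a1 at 2.52 against 1.76. Without the expression filter the stromal median was 0.011 (percentile 71.8). Neutrophil markers were higher in 3 of 5 members (median 0.20, percentile 99.7), with S100a9 at 8.38 against 6.66 FPKM, a ratio of 1.26 whose interval (0.932 to 1.73) includes no difference. With a mean FPKM of at least 5 the neutrophil percentile was 88.6. Monocyte and macrophage markers (median 0.038, percentile 96.2) and the dendritic cell list (median 0.082, percentile 96.0) lay within the range of random lists. In the sparsely measured cell type lists, Cd4 was at 11.8 FPKM with Ift88 shRNA against 12.3, Pf4 at 315 against 309, Kdr at 5.89 against 4.83 and Vwf at 22.4 against 21.8.

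Sterol synthesis, cell cycle, immediate early and cytoskeletal genes were also higher with Ift88 shRNA. The cholesterol and lipid list was higher in 19 of 30 members (median 0.16, above every random list), with Lss, which encodes lanosterol synthase, at 12.5 against 9.09 FPKM. In the same list the cholesterol exporter Abcg1 (14.1 against 19.1 FPKM) and the fatty acid binding protein gene Fabp4 (172 against 226) were lower. Cell cycle genes were higher in 25 of 34 members (median 0.089, percentile 99.9), with the cyclin gene Ccna2 at 11.95 against 9.76 FPKM and the mitotic kinase gene Plk1 at 9.09 against 7.55. Immediate early genes were higher in 13 of 21 members (median 0.099, percentile 99.8). Among them Fos, a subunit of the AP-1 transcription factor, was at 13.1 against 8.09 FPKM, a ratio of 1.62 (1.45 to 1.801). Actin cytoskeleton genes were higher in 21 of 28 (median 0.070, percentile 99.9), with the focal adhesion gene Vcl at 14.6 against 12.4 FPKM.

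Interferon-stimulated genes were higher with Ift88 shRNA in 25 of 32 members (median 0.095, percentile 99.99), with Oas3 at 28.3 against 23.7 FPKM and Isg15 at 34.7 against 29.98. NRF2 targets were higher in 17 of 26 (median 0.055, percentile 99.6), with the metallothionein gene Mt2 at 118 against 86.0 FPKM; after centring for length and GC content their percentile was 97.0, inside the range of random lists. Ribosomal protein genes were lower in all 32 members, by small amounts (median -0.11, percentile 0.01), with Rpl5 at 201 against 224 FPKM. With equal library totals 29 of the 32 were lower.

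The other 16 lists lay within the range of random lists in the knockdown comparison. Of these, inflammatory genes stood apart on the higher side in 3 of 8 alternatives, dendritic cell genes in 2, and macrophage markers and mechanosensitive channels in 1 each. Cilium genes other than Ift88 had a median of 0.017, with 18 of 35 higher; Dync2li1, a subunit of the retrograde cilium motor, was at 3.12 against 1.86 FPKM. Hedgehog pathway genes had a median of 0.070 over 5 members, with the receptor gene Ptch1 at 1.23 against 1.52 FPKM. Mechanosensitive channels and receptors (median 0.065, percentile 97.1) and YAP and TAZ targets (median 0.093, percentile 97.0) were close to the limit. Osteoclast-derived coupling factors had a median of 0.028, with the complement gene C3 at 98.4 against 69.9 FPKM and the BMP antagonist gene Grem1 at 1.85 against 0.972. Medians were -0.014 for the Wnt pathway, 0.051 for the BMP and TGF-beta pathway, 0.060 for inflammatory cytokines and chemokines and 0.013 for negative regulators of osteoclast formation. They were 0.043 for hypoxia and glycolysis, 0.011 for the unfolded protein and integrated stress response, 0.024 for p53 targets, -0.025 for oxidative phosphorylation and 0.0070 for housekeeping controls.

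Among single genes, 8 were at least 2-fold higher and 7 at least 2-fold lower with Ift88 shRNA, of which 3 and 6 were small RNA genes. Fxyd2, a regulatory subunit of the sodium/potassium ATPase, was at 37.8 FPKM against 9.98 in the sheared control, a ratio of 3.78 (3.17 to 4.54). Cxcl2 was at 3.40 against 1.13 FPKM (ratio 3.01, 2.06 to 4.49) and Mt3 at 5.57 against 1.99 (ratio 2.79, 1.72 to 4.55). Mmp9 completed the higher genes apart from Gm4070, a copy of the interferon-inducible GTPase gene Gvin1 whose sum with Gvin1 was 4.82 FPKM in the sheared control and 4.92 with Ift88 shRNA. Eif3j2, the uncertain copy described above for shear, was the only gene other than small RNA genes at least 2-fold lower. Ift88 itself did not reach 2-fold on the log2(FPKM + 1) scale, at -0.76, because its FPKM is low.

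In the knockdown comparison, 94.5% of genes were within 1.2-fold and the robust SD of the log2 ratio was 0.109. Of the 28 lists placed, 12 stood apart, 11 higher and 1 lower, against 1.4 by chance if genes were independent, and 9 did so under every alternative. This count is not separate from that for shear, since both ratios use the sheared control library. The osteoclast, fusion, matrix, interferon, stromal, neutrophil and ribosomal lists had stood apart in the opposite direction under shear. Cell cycle, cholesterol and NRF2 lists stood apart on the higher side in both, and immediate early and actin lists in the knockdown comparison only. Because static cells with Ift88 shRNA were not analysed here, these differences combine any effect of the knockdown in resting cells with any effect on the response to shear. They also include differences between single cultures and library preparations, and any off-target effect of the hairpin.

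**Figure D2:**
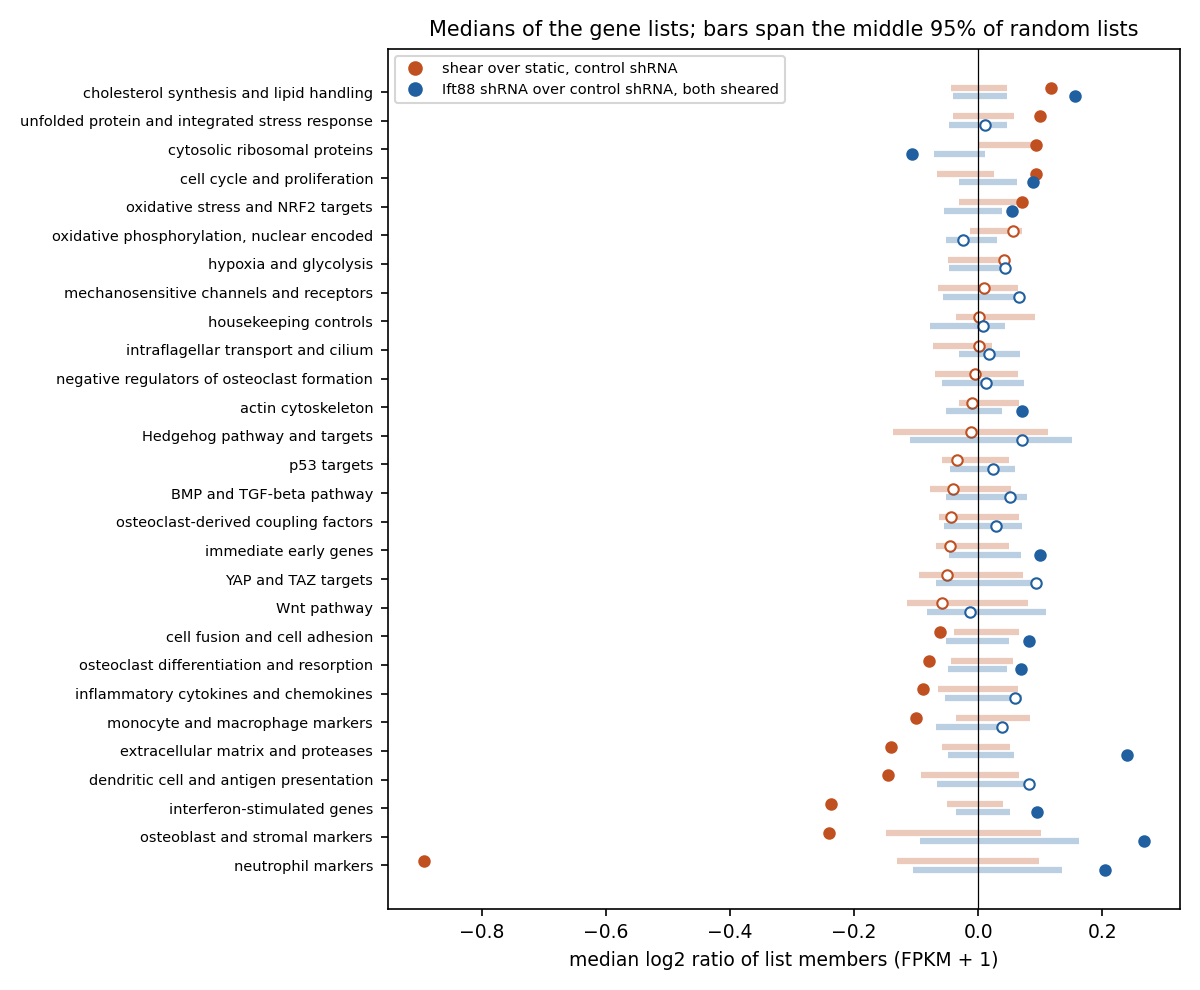
Median log2 ratio of each gene list (horizontal axis) in the shear and knockdown comparisons, with bars for the middle 95% of 10000 random lists matched on expression and filled points for lists standing apart. The osteoclast list lay at -0.080 under shear and 0.070 in the knockdown comparison, and interferon-stimulated genes at -0.24 and 0.095.

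Whether the knockdown library returned toward the static library was examined by setting both ratios side by side. Across the 10358 genes they had a Pearson correlation of -0.49 and a Spearman correlation of -0.22, where 3 simulated unchanged libraries gave -0.50 and -0.48, because both ratios use the sheared control library. The covariance was -0.0262 against -0.00608 in simulated libraries. Without the small RNA genes the Pearson correlation was -0.26 and the covariance -0.00496 against -0.00610, so the excess came from small RNA genes. Genes are not independent replicates in these values. The simulated noise was set from the observed ratios and was alike in all 3 libraries. Since the observed Spearman correlation was weaker than the simulated one, the simulated values are a rough guide only. Of the 17 genes at least 2-fold lower under shear, 11 were higher in the knockdown comparison (64.7%, exact interval 38.3% to 85.8%, 94.4% in simulated libraries). Of the 12 at least 2-fold higher, 9 were lower (75%, 42.8% to 94.5%, 96.6% in simulated libraries). Neither share was above that of unchanged libraries. Selecting extreme genes on a ratio that shares a library gives a high share by itself. The shares therefore cannot show whether these genes returned toward the static library.

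By the robust SD and the share of genes within 1.2-fold, the sheared Ift88 shRNA library lay further from the static library than the sheared control did. The robust SD was 0.137 with 90.7% of genes within 1.2-fold, against 0.111 and 95.8% for shear. The plain SD, which extreme genes weigh on more, did not follow this, at 0.237 against 0.253 for shear. Counts at 2-fold did not either, at 9 higher and 13 lower against 12 and 17 for shear. Compared directly, the sheared Ift88 shRNA library and the static library differed in both directions across osteoclast genes. The osteoclast list had 13 members higher and 14 lower, with a median of -0.0079 (percentile 33.0) over members that offset each other. Acp5 stood at 83.0 against 97.7 FPKM, Mmp9 at 85.5 against 70.3, Dcstamp at 7.27 against 5.21, Itgb3 at 8.12 against 5.36, Slc9b2 at 1.05 against 1.75, and Ctsk at 18.5 against 29.4. The sheared control library was the lowest of the 3 for 16 of the 27 osteoclast genes (59.3%), compared with 32.9% of all genes. This was not particular to osteoclast genes, since the share was 75% for interferon-stimulated genes, 85.7% for stromal markers (6 of 7), 70% for the dendritic cell list, 64.7% for inflammatory genes and 60% for neutrophil markers (3 of 5). Ribosomal protein genes went the other way. The sheared control library was the highest of the 3 for 31 of 32 of them (96.9%), compared with 25.3% of all genes. Extracellular matrix genes (median -0.024) and stromal markers (median -0.021) also lay within the range of random lists in this direct comparison.

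Other groups differed from static cells in both sheared libraries. Both ratios use the same static library, so a difference in both is not a repeat of a shear effect. Interferon-stimulated genes were lower than in static cells in both sheared libraries for 29 of 32 members, compared with 37.4% of all genes, and the median of the Ift88 shRNA library over the static library was -0.16, below every random list. Neutrophil markers were lower in both sheared libraries in all 5 members (median -0.69 with Ift88 shRNA, -0.19 without the filter). Monocyte and macrophage markers had a median of -0.10 (percentile 0.14). Cell cycle genes (median 0.17) and the cholesterol and lipid list (median 0.29) stood further above the static library than in the sheared control, both above every random list. NRF2 targets (0.16) and the stress response list (0.12) stood apart on the higher side as well, as in the sheared control. Immediate early genes (0.13), hypoxia genes (0.071) and cilium genes (0.055) stood apart on the higher side with Ift88 shRNA only. In the sheared control over static cells their medians were -0.045, 0.042 and 0.0011, within the range of random lists. The hypoxia result was lost with centring for length and GC content, and the cilium result in 3 of 8 alternatives, with a median of -0.0047 at a mean FPKM of at least 5. In this comparison, which differs in shear and in knockdown at once, 9 genes were at least 2-fold higher and 13 lower.

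**Figure D3:**
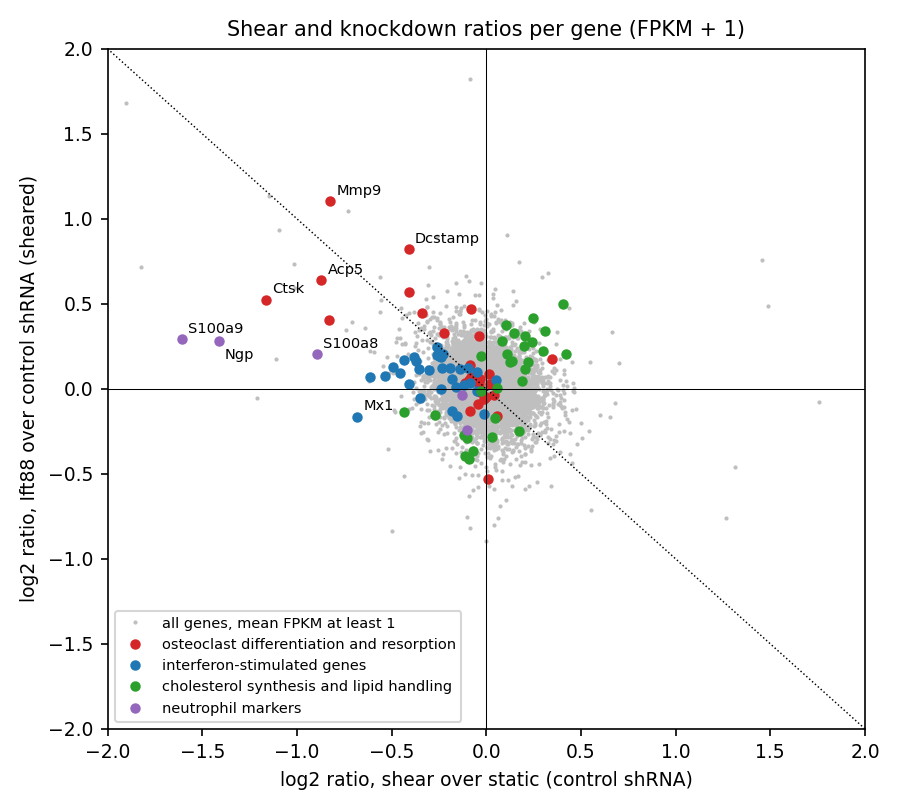
Log2 ratio of sheared over static control cells (horizontal axis) against the log2 ratio of Ift88 over control shRNA under shear (vertical axis), with 1 point per gene, colours for 4 gene lists, selected genes named and a dotted line where the ratios are equal and opposite. Axes end at 2 in both directions, leaving 16 genes outside, and both ratios use the sheared control library, which alone gives a correlation of -0.50 in simulated unchanged libraries.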

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

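The pseudocounts, filters and scalings were planned before the data were examined; leaving out small RNA genes, the 1.5-fold limit and the centring for length and GC content were chosen after the results were seen. In the shear and knockdown comparisons, no list standing apart reversed its direction under any alternative that could place it. No named gene at least 2-fold different did so either, but single genes were not run with the centring for length and GC content, and small RNA genes, outside the rule for named genes, were not run singly. For Ift88 shRNA over static cells, the cilium median went from 0.055 to -0.0047 with a mean FPKM of at least 5. At the 2-fold limit, neither scaling changed a count by more than 1.5 times. With a pseudocount of 0.1, 16 genes were higher and 12 lower in the knockdown comparison, 15 were higher in Ift88 shRNA over static cells, and Ift88 was at -1.11. With a pseudocount of 5, 8 genes were lower under shear, 5 were higher in the knockdown comparison and 4 were higher in Ift88 shRNA over static cells. In that setting 37.5% of the genes lower under shear were higher in the knockdown, and Ift88 was at -0.31. A larger pseudocount shrinks the ratios of low genes by construction. With a mean FPKM of at least 5, which tests fewer genes, 7 were higher and 9 lower under shear, 4 were higher in the knockdown comparison, and 3 were higher and 8 lower in Ift88 shRNA over static cells. Without small RNA genes the counts were 4 higher and 9 lower under shear, 5 and 1 in the knockdown comparison, and 5 and 5 in Ift88 shRNA over static cells. The share of genes lower under shear and higher in the knockdown was then 88.9%, that of genes higher under shear and lower in the knockdown 50% (2 of 4), and the correlation -0.26. At 1.5-fold, 30 genes were lower under shear, 29 higher and 21 lower in the knockdown comparison, and 35 higher and 42 lower in Ift88 shRNA over static cells. Over the list medians of the shear and knockdown comparisons, 423 of 444 values kept their call and 21 did not. Over all named genes, 1504 of 1550 ratios moved by less than their counting error (or 0.1 where it could not be estimated) and 46 moved by more. The cause was not tested. With a pseudocount of 5, several medians shrank by over 1.5 times while their lists still stood apart, such as cell cycle genes at 0.056 under shear and 0.057 in the knockdown comparison. The immediate early median over static cells ranged from 0.056 to 0.21. The number of lists standing apart in the shear and knockdown comparisons stayed within 1.5 times under every alternative. No gene symbol occurred more than once, so the planned choice between repeated symbols was not run, and leaving out a replicate is not possible with 1 library per group. No paired analysis was possible because each group had 1 library. At these estimated depths, counting intervals were still wide for genes of a few FPKM, such as Mt3 under shear (5.63 and 1.99 FPKM, 0.216 to 0.573). The intervals leave out variation between cultures, which 1 library per group cannot show.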

Other observations

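The split of the lipid list, all tests in this part and the genes it names outside the rule for named genes were chosen after the results were seen. The cholesterol and lipid list held members that went in opposite directions. Of its 30 measured members, 14 encode enzymes of sterol synthesis and 10 act in lipid efflux, uptake or storage. All 14 synthesis enzymes were higher in sheared Ift88 shRNA cells than in sheared control cells (median log2 ratio 0.28), and 13 of 14 were higher in sheared control than in static cells (median 0.20). Against static cells the Ift88 shRNA library had a median of 0.50. Sqle, a rate-limiting enzyme of sterol synthesis, was at 24.4 FPKM in static, 28.2 in sheared control and 35.3 in sheared Ift88 shRNA cells, and Hmgcs1 at 26.0, 28.0 and 36.6. All 10 efflux and handling genes were lower with Ift88 shRNA than in the sheared control (median -0.28), and 8 of 10 were lower in sheared control than in static cells. Abcg1, an exporter induced by the oxysterol receptor LXR, was at 20.4, 19.1 and 14.1 FPKM, Apoe at 3780.2, 3599 and 2788, and Abca1 at 14.5, 10.51 and 9.45.

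Some genes set the Ift88 shRNA library apart from both control shRNA libraries. At a 1.5-fold limit and without small RNA genes, 8 genes were higher and 10 lower than in both, the lower group including Ift88. These include H2-Q6 and Eif3j2, whose values are uncertain. By the same rule, 6 genes were higher and 7 lower in both sheared libraries than in the static library. The sheared control library was lower than both others for 7 genes and higher for 1. Fxyd2 was at 10.7, 9.98 and 37.8 FPKM in the static, sheared control and sheared Ift88 shRNA libraries, and the TGF-beta-induced matrix gene Tgfbi at 11.7, 13.3 and 23.0. Alox5, which encodes the enzyme that starts leukotriene synthesis, was at 1.09, 1.56 and 3.05 FPKM, and the secreted glycoprotein gene Olfm1 at 2.64, 2.94 and 6.37. Asah1, which encodes lysosomal acid ceramidase, was at 126, 130 and 74.1 FPKM (its end overlaps the gene Frg1), and the lymphocyte activation family gene Slamf7 at 15.8, 14.8 and 7.97. Tma7 (132, 138 and 80.9 FPKM) and Cdc5l (24.0, 22.8 and 14.8) were also lower. An off-target effect of the hairpin and an effect of losing Ift88 were not compared, since 1 Ift88 hairpin library was analysed.

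Many osteoclast genes were lower in the sheared control library than in the other libraries. Counting error alone would place the shear median of the osteoclast list between -0.012 and 0.012, and the observed -0.080 lies outside; centring for transcript length and GC content left the list at percentile 0.02, which argues against such a trend as the whole cause. A larger share of other cells would raise their markers, whereas 4 of 4 other cell type lists (macrophage, dendritic, stromal and neutrophil) stood apart on the lower side. That count was known when the comparison was chosen, so it does not exclude a change in cell shares. The macrophage list does not mark other cells alone, since its member Lyz2 was the most abundant gene in every library (5.76%, 5.39% and 5.74% of total FPKM). The dendritic list was placed without Flt3, Zbtb46, Xcr1, Clec9a, Cd209a and Ccr7, which did not pass the expression filter. It rested on genes such as Itgax and Cd74 and may not mark other cells alone either. The count also cannot speak to a larger share of less differentiated precursors or of cell types outside these lists. Without the expression filter the dendritic and stromal lists no longer stood apart, although no median among these lists was above 0 in any alternative that could place it. A response to shear that needs Ift88 may account for the pattern, as may a difference between single cultures in how far they had differentiated. Lower levels under shear together with a separate effect of the Ift88 hairpin that is independent of shear may do so as well. These cannot be told apart with 1 library per group and without static cells carrying Ift88 shRNA. The median of Ift88 shRNA over static cells, -0.0079, decides nothing, since Ctsk and Slc9b2 stayed below static cells while Itgb3 and Dcstamp lay above.

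Neutrophil granule transcripts were lower in both sheared libraries. Ltf, which encodes lactoferrin, was at 1.23, 0.431 and 0.344 FPKM in the static, sheared control and sheared Ift88 shRNA libraries, and Camp at 0.703, 0.136 and 0.136. Counting error does not account for all of this. Of 9 neutrophil list members with at least 10 estimated static fragments, 6 had intervals below the static level in both sheared libraries (S100a9, Ltf, Camp, Ngp, Csf3r and Lcn2). Mmp8, Cebpe and Cxcr2 did not. The 6 include Csf3r, a receptor rather than a granule gene, whose interval under shear reached 0.994. Members were admitted by their static fragments and both intervals use that library, which can by itself favour values below it. Fewer carried-over neutrophils in the swirled dishes may explain the lower levels, as may lower expression in the same cells. A difference between single cultures may do so as well, since both ratios use the same static library. Under shear Ltf was at 0.351 and Ngp at 0.232 times the static level, but Csf3r at 0.926 and Mmp8 at 0.904. Bulk RNA leaves cell number and expression per cell open. The most abundant list members, S100a8 (24.2, 12.6 and 14.6 FPKM) and S100a9, are also expressed by monocytes.

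Short RNA genes made up much of the list of single genes with large differences. Of the 35 genes at least 2-fold different in either main comparison, 51.4% had a mean transcript length under 200 bases, compared with 0.0194% of the other 10323. Mir684-1 was listed at 458 FPKM in static cells and at 0 in both sheared libraries, and Mir7-1 at 202 FPKM in the sheared control and 0 in the others. This is consistent with genes shorter than the sequenced fragments, for which a few fragments give a large FPKM, so these values may not reflect the microRNAs. No biological explanation was tested for these genes.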
